A study of Arabidopsis thaliana with 6 samples.

How the data were processed

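Total RNA from whole Arabidopsis seedlings was labelled as biotinylated cRNA and hybridised to 1-colour Affymetrix arrays, per the labels' protocols. The deposited values are linear signal intensity values per probe set, made by the authors with MAS5, per the submitters' processing notes; its version and settings are not given in the sources used here. The trimmed mean of each array, without the lowest and highest 2% of values, was 500.04, so the arrays had been scaled to a common level before deposit. MAS5 scaling makes every level relative to the rest of its array, so a shift of all transcripts would not be seen. No detection calls were used here, and low signals may not differ from background.

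Groups and replicate numbers came from the sample titles, which call the samples biological replicates: 3 of Col and 3 of hub2-3. The probe table gave 1 gene for 13513 probe sets, several genes for 503 and no name for 8730; 64 control probe sets were left out. Symbols were updated through gene IDs from the TAIR10.1 annotation, where 13436 of the probe sets with 1 gene matched. It was used only for names, chromosome, gene order and gene span, since the sources used here name no build. HUB2 and HUB1 are unnamed in the probe table, so their levels, planned as results, are not analysed here.

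Signals were taken to log2 with no offset. The 30% of probe sets with the lowest mean log2 signal (a signal under 53.6) were left out, and the brightest probe set with exactly 1 gene was kept per gene, which left 8570 genes. Each gene was tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend, 2-sided) and Benjamini-Hochberg adjustment, calling an adjusted p under 0.05. The median SE of a log2 ratio was 0.117. Tested on simulated data for this comparison (200 changed of 8570 genes), the fit recovered 59.1% of genes changed by a log2 ratio of 0.5, 92.8% at 1 and 99.7% at 2, and 4.17% of its calls were false. The simulated genes varied independently of each other, with a spread that followed mean signal. These shares therefore do not cover genes that vary together.

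Before the data were examined, 26 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule took, among genes that passed and whose groups did not overlap, the 12 that rose most and the 12 that fell most, and from each list up to 4 members by smallest p; PSBW's list mates RCA and LHCB4.1 were named after their values were seen. Of 404 list genes, 40 were measured; 9 lists had no measured member, and the 5 lists with at least 3 were tested with camera (limma) at its preset correlation of 0.01, adjusted over the 5. The alternatives changed the filter, log offset, scaling, variance prior, replicate block, replicates, probe sets, list correlation and list test. Gene families defined from symbols, a hypoxia-responsive list written from memory, and the search for runs of neighbouring genes were added after the data were seen. Runs were searched as the stretch with the largest sum of log2 ratio minus 0.5, and windows of 20 measured genes were set against 1000 shuffles of gene order. The stretch was also delimited on every other gene of the chromosome and measured on the genes between, both ways.

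RNA quality was measured as the mean log2 ratio of 3 prime over 5 prime control probe sets. It was 0.97 ± 0.04 in Col and 1.10 ± 0.12 in hub2-3 (SD, n = 3, 2-sided exact permutation p = 0.3). Single controls went both ways. The second actin control was higher on all 3 hub2-3 arrays, by 0.17, and the first ubiquitin control lower on all 3, by 0.11 (2-sided exact permutation p = 0.1 for each). The other controls had p of 0.3 to 0.9 in the same test. The share of probe sets under the low signal was 29.3% ± 0.37 in Col and 29.2% ± 0.34 in hub2-3 (2-sided exact permutation p = 0.6). The bound puts this share near 30% by design, so only its difference between genotypes is informative. The 25S rRNA control was lower on all 3 hub2-3 arrays, at a log2 signal of 6.02 ± 0.82 against 7.34 ± 0.20 (2-sided exact permutation p = 0.1). The smallest p that 3 arrays against 3 allow is 0.1. Figures were drawn with matplotlib 3.10.9.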

Results

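Gene expression was compared between Arabidopsis seedlings of the hub2-3 mutant and the wild type Col, with 3 biological replicates of each genotype. HUB2 is an E3 ubiquitin ligase that monoubiquitinates histone H2B. Whole seedlings 12 days old, grown under constant white light, gave 1 array each, so 6 arrays held 22810 probe sets. Median signals lay between 210.8 and 216, and the arrays of a genotype correlated at 0.981 to 0.988 across genes, against 0.972 to 0.977 between genotypes. The number of arrays limits the precision of every value. HUB2 and HUB1 carried no name in the probe table used here, so the level of the mutated gene was not analysed here and the genotype labels were not checked against it.

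The comparison of hub2-3 with Col asked which transcripts differ between the mutant and the wild type. QQS, an Arabidopsis-specific gene linked to leaf starch content, rose most among the named genes, from a signal of 89.0 ± 17.3 in Col to 496 ± 101 in hub2-3 (SD, n = 3), which was 5.57-fold. COR27, a cold-regulated gene tied to the circadian clock, rose 4.02-fold from 183 ± 4.16 to 742 ± 119.6, and COR15B, a cold-induced chloroplast protein, rose by a log2 ratio of 0.89 ± 0.15 (SE). AT4G33720, of the PR-1-like secreted protein family, fell most, from 4204 ± 333 to 681 ± 21.8, or 6.16-fold. LHCB4.2, an antenna protein of photosystem II, fell 1.77-fold, and BCAT4, an enzyme of methionine-derived glucosinolate synthesis, fell 1.58-fold. In all, 367 of 8570 genes were higher and 383 lower in hub2-3 at an adjusted p under 0.05 (limma), and 33 and 27 of these changed at least 2-fold.

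Among the 12 genes that rose most, AT3G53250 had a log2 ratio of 1.82 ± 0.17 (SE), AT1G07050 of 1.76 ± 0.16 and AT5G45310 of 1.63 ± 0.24. AGL80, a MADS-box factor known from the central cell of the ovule, rose by 1.56 ± 0.28 from a low signal of 37.0 ± 12.2. The peroxidase gene AT5G64120 rose by 1.40 ± 0.13 (adjusted p = 3.24e-05). AT3G05320, AT4G26490, AT1G09500, AT3G46700 and AT3G19550 rose by 1.36, 1.34, 1.31, 1.21 and 1.21 on the log2 scale. AT4G26490 belongs to a stretch of neighbouring genes on chromosome 4 that were higher together.

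Among the 12 that fell most, AT5G35940 had a log2 ratio of -1.76 ± 0.22, AT3G29970 of -1.74 ± 0.12, AT2G43140 of -1.70 ± 0.27 and AT4G22610 of -1.66 ± 0.18. AT5G23840, AT5G10040 and AT1G06620 followed at -1.40, -1.39 and -1.34. AT4G39675 fell from 2293 ± 139 to 964 ± 127 (adjusted p = 9.31e-06), and AT2G19660 had a log2 ratio of -1.25 ± 0.19. AT2G43620, of a chitinase family, and AT5G18430, a GDSL lipase, both had a log2 ratio of -1.24. In AT5G45310, AGL80, AT3G05320 and AT3G46700 the Col mean, and in AT5G35940, AT2G43140 and AT5G23840 the hub2-3 mean, lay under the signal of 53.6 used as the filter bound, so the size of these changes rests on signals that can be near background. All 750 genes that passed had 3 hub2-3 values beyond all 3 Col values, as did 29.1% of the genes tested, where chance gives 10%.

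**Figure D1:**
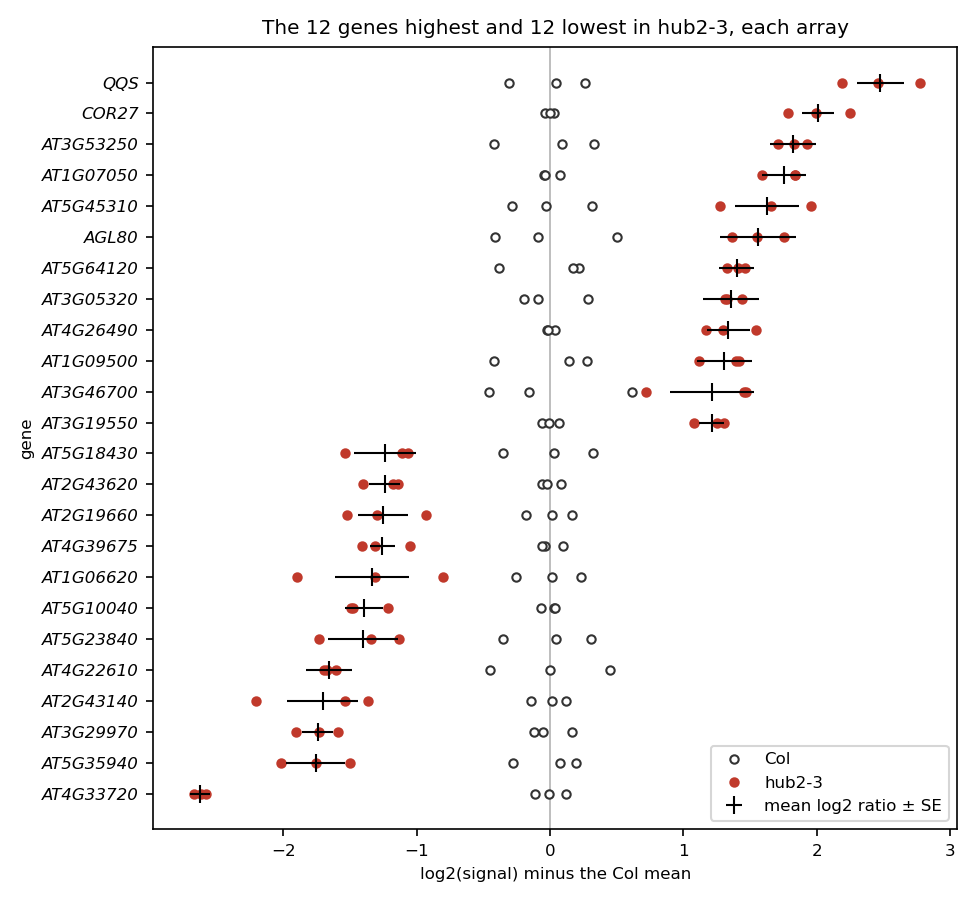
Log2 signal of each array minus the Col mean (x axis) for the 12 genes that rose most and the 12 that fell most in hub2-3 (y axis). Open points are Col arrays, filled points hub2-3 arrays, and ticks with bars the log2 ratio ± SE. QQS stands at 2.48 and AT4G33720 at -2.62. The points of the genotypes do not overlap in any of the genes, since the rule that chose them required this.

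Of 35 genes in the photosynthesis list, 6 were measured, and these fell as a group in hub2-3. Of the 6 measured members, 4 were lower and 0 higher, with a median log2 ratio of -0.31 (camera, adjusted p = 0.00256 over 5 lists). With an estimated correlation the call was lost (adjusted p = 0.118). The estimate was -0.038, below the preset value, so the loss does not reflect members that vary together more than preset. With the preset correlation, camera takes its degrees of freedom from the number of genes, and with an estimate from the 6 arrays. The preset p therefore does not reflect how few arrays there were. Adjusted over the list alone, 4 members were also lower. The members that fell were LHCB4.2 at -0.82 ± 0.07 (SE), the photosystem I subunits PSAN at -0.43 ± 0.06 and PSAE-1 at -0.33 ± 0.06, and the photosystem II subunit PSBW at -0.29 ± 0.07. LHCB4.1 at -0.15 ± 0.07 and RCA, which activates Rubisco, at 0.02 ± 0.07 did not pass.

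Of 16 genes in the auxin list, 3 were measured. Of these, 1 was lower over all genes tested and 3 were lower adjusted over the list alone, with a median of -0.41. The list passed at the preset correlation (camera, adjusted p = 0.0257) and not with an estimated one (camera, adjusted p = 0.353). That estimate was 0.756, against the preset 0.01, so the passing p treats members that varied together as nearly independent. GH3.3, which joins auxin to amino acids, fell by a log2 ratio of 0.41 ± 0.10. WES1, a related enzyme, stood at -0.23 ± 0.07 and the Aux/IAA gene IAA29 at -0.49 ± 0.16, and neither passed over all genes. Of 7 tubulin genes measured from a list of 15, TUB7 was lower at -0.34 ± 0.08 and 6 did not pass, while 3 were lower adjusted over the list alone. The list itself did not pass (camera, adjusted p = 0.081), nor did it with an estimated correlation (camera, adjusted p = 0.353). It passed with no signal filter (adjusted p = 0.0487) and with fry (adjusted p = 0.0444), which tests for a shift from 0 and not against other genes. The 3 root markers, PYK10, EXPA7 and EXPA18, had log2 ratios of -0.03, -0.04 and -0.03 (adjusted p of the list = 0.933), and 0 of them passed over the list alone. The 6 measured histone H2B genes had a median of -0.01 and a mean of 0.02, ranged from -0.18 for HTB4 to 0.28 for HTB2, and 0 passed over all genes or over the list alone (adjusted p of the list = 0.933).

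**Figure D2:**
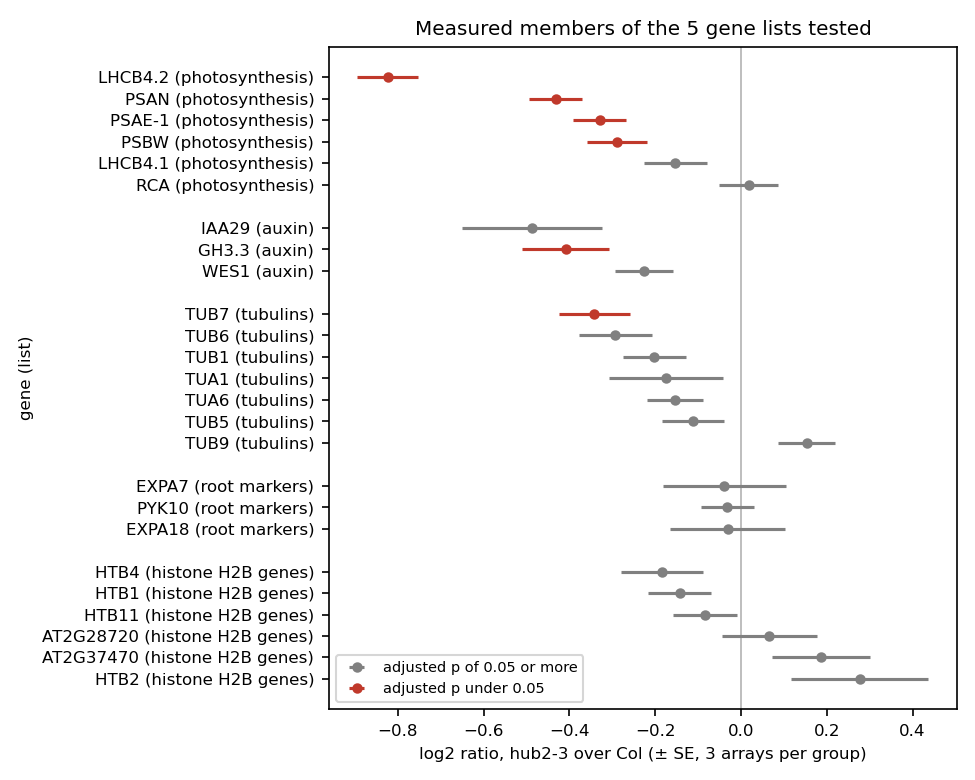
Log2 ratio of hub2-3 over Col with its SE (x axis, 3 arrays per group) for each measured member of the 5 gene lists tested (y axis). Red points passed an adjusted p of 0.05 over all genes and grey points did not. LHCB4.2 lies farthest from 0 at -0.82, and the root markers lie near 0.

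Other lists had 1 or 2 measured members and were not tested as groups. COR15B passed, while COR47, another cold-induced gene, stood at 0.05 ± 0.07. The clock gene GI stood at 0.09 ± 0.09, UBP26, a protease that removes ubiquitin from H2B, at 0.03 ± 0.13, and the light-signalling factor HYH at 0.01 ± 0.14. AGL24, a promoter of flowering, had a log2 ratio of -0.28 ± 0.12 (adjusted p = 0.17). The defence genes PDF1.2 at -0.47 ± 0.17 and SAG101 at -0.11 ± 0.26, the stomatal regulators SPCH at -0.37 ± 0.13 and FMA at -0.16 ± 0.14, and the Aurora kinases AUR1 at -0.18 ± 0.11 and AUR2 at -0.29 ± 0.17 did not pass. Nor did DFR, of anthocyanin synthesis, at -0.13 ± 0.22, or STZ, a stress-induced zinc finger gene, at -0.12 ± 0.13.

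A stretch of chromosome 4 from AT4G25660 to AT4G26555, noticed only after its values were seen, held 33 measured genes in a row that were all above 0, with a median log2 ratio of 0.87, or 1.83-fold. Of these, 30 passed as higher and 0 as lower, and 11 of the 33 genes that rose at least 2-fold in hub2-3 lay in it. The median was 0.87, 0.90 and 0.89 in hub2-3 replicates 1, 2 and 3, each against the Col mean. The 20 measured genes on either side had medians of -0.13 and -0.07. When the fit and the adjustment were repeated without the stretch, 329 genes were higher and 380 lower, so some genes outside it also lost their call.

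**Figure D3:**
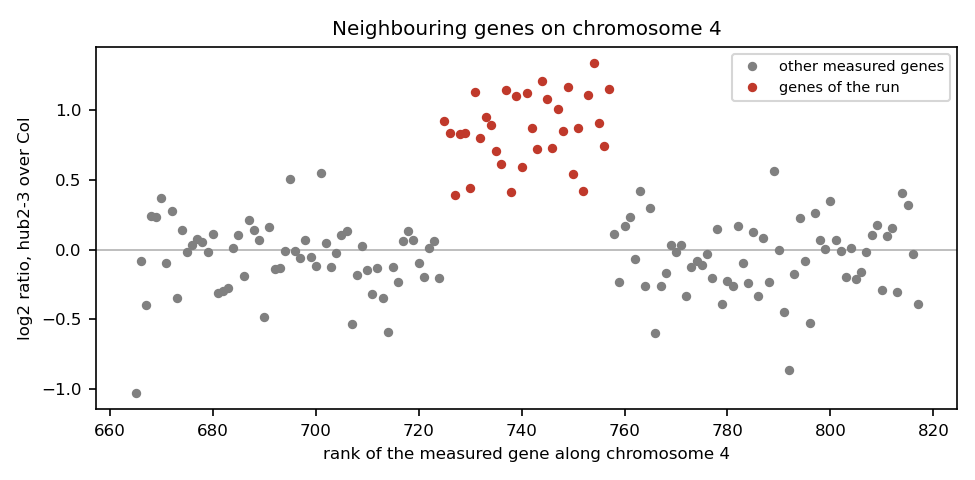
Log2 ratio of hub2-3 over Col (y axis) of each measured gene by its rank along chromosome 4 (x axis, gene order and not distance). Red points are the 33 genes of the stretch, at 0.39 to 1.34, and grey points are neighbouring genes on both sides.

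The counts fell by over 1.5 times without Col replicate 1 (202 higher and 205 lower), Col replicate 2 (203 and 209) or Col replicate 3 (219 and 230), and without a trend in the variance prior (216 and 212). Calls of PSBW, GH3.3 and TUB7 were each lost in 6 of 16 alternatives, and that of AT3G46700 in 6 of 15. PSAE-1 lost its call in 2 of 16, BCAT4 in 1 of 16 and AT1G06620 in 1 of 15. The auxin list's call was lost without hub2-3 replicate 1 (camera, adjusted p = 0.0703) or 2 (camera, adjusted p = 0.0559).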

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

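The count over unnamed probe sets was chosen after the data were seen; the splits of the arrays were set before their result was seen.

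Probe sets with no gene name here lie outside the comparison of named genes, and many of them differed. When each of 15922 probe sets, named or not, was tested in the same way, 510 unnamed probe sets were higher in hub2-3 and 442 lower, of 6926 tested (13.7%). The unnamed probe set that rose most went 3.93-fold higher, from a signal of 782 ± 114 to 3065 ± 313 (SD, n = 3), and the next rose 3.67-fold. The one that fell most went from 235 ± 9.10 to 64.2 ± 20.5, and the next from 187 ± 23.5 to 49.9 ± 9.84.

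The real grouping of the arrays called 750 genes, and the highest of the other splits called 1; 1 of the 10 splits, the real one itself, gave that many, and 10 splits are too few for a share under 0.05.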

How the results depend on the processing

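Counts over probe sets named or not, counts without the stretch on chromosome 4, and gene family tests were chosen after the data were seen. Across alternatives, 362 of 369 values of the 24 top genes kept their direction and their side of the threshold, 7 lost the call and 0 reversed; of 523 values of 33 list genes, 479 kept both, 21 lost the call, 8 gained one and 15 changed sign. Without the lowest 50% of probe sets, 15 genes were at least 2-fold higher and 13 lower, from fewer genes tested. Without a trend in the variance prior 216 were higher and 212 lower; the cause was not tested. Over every probe set, 944 were higher and 919 lower, 67 and 54 of them at least 2-fold, from more features. Leaving out 1 array gave 202 to 306 higher, 205 to 371 lower, 27 to 33 at least 2-fold higher, 24 to 40 at least 2-fold lower, and 1 to 2 lists passing, with fewer arrays; counts of genes higher or lower fell by over 1.5 times without each Col array (407, 412 and 449 calls without replicates 1, 2 and 3) and by less without a hub2-3 array, while 1 list passed without hub2-3 replicate 1 or 2. With no signal filter, and with fry, 3 lists passed, tubulins added. With an estimated correlation 0 lists and 0 families passed. The estimate lay below the preset value for the photosynthesis list and the calmodulin-like genes, and above it for the auxin list and the mitochondrial genome. With replicate number as a block, 307 genes were higher and 360 lower, and PDF1.2 and TUB6 passed; same-numbered arrays deviated with correlations of -0.06, -0.01 and -0.06, so the numbers are not taken to pair the samples. The RNA quality difference of 0.13 moved to 0.47 with the first actin control alone and to -0.11 with the first ubiquitin control alone; the cause was not tested.

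Values that changed sign did not pass in either setting. PYK10 stood at 0.068 after quantile normalization. Without 1 array in turn, HYH ranged from -0.052 to 0.106, UBP26 from -0.078 to 0.104, DFR from -0.313 to 0.020, SAG101 from -0.325 to 0.229, EXPA7 from -0.162 to 0.085, EXPA18 from -0.144 to 0.110 and STZ from -0.231 to 0.019. The root marker median ranged from -0.144 to 0.085 and the H2B gene median from -0.039 to 0.032. The cause was not tested. The alternatives for the HUB2 level were not run. Signals near background limit the genes of low signal. The share of probe sets in Col under the low-signal bound, 29.3%, does not measure this, since the bound was set to leave out the lowest 30%.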

Other observations

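Of the tests below, those of the stretch on chromosome 4, of the mitochondrial transcripts and of gene length were chosen after their values had been seen in part or whole; the test of scaling for the hypoxia-responsive genes was also chosen after their values were seen, and the test of how their members were picked was set before the members not yet looked at were read. The gene families and the hypoxia-responsive list were added after the data were seen.

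Of 27 gene families defined from symbols, several held members that moved apart. Of 8570 genes tested, 7357 carried only a locus name and could not be matched by symbol. A family matched by symbol therefore stands for its named members only. Of 11 glutathione transferases, GSTU25 rose 1.86-fold and GSTU22 1.63-fold, while GSTU20 fell 1.47-fold. Of 7 xyloglucan endotransglucosylases, which remodel cell walls, XTH20 and XTH33 rose by log2 ratios of 0.68 and 0.65 and XTH16 fell by 0.54. Of 30 UDP-glycosyltransferases, UGT73B4 rose 1.91-fold and UGT76E11 1.53-fold, and UGT76C1, UGT88A1 and UGT74B1 fell. AGL80, AGL16 and AGL87 rose among 7 AGAMOUS-like genes, and CYP71B22 and CYP71B23 fell among 13 cytochrome P450 genes. None of these families passed as a group (camera, adjusted p of 0.301 for the AGAMOUS-like genes, 0.652 for the xyloglucan endotransglucosylases and P450 genes, 0.899 and 0.914 for the UDP-glycosyltransferases and glutathione transferases).

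The 6 measured genes with a calmodulin-like symbol, which encode calcium sensors, fell as a group, with a median of -0.44 (camera, adjusted p = 0.00114). CML38 and CML30 passed as lower at -0.58 and -0.59, and 4 of 6 did not pass. The call was lost with an estimated correlation (camera, adjusted p = 0.212). That estimate was -0.13, below the preset value, so the loss does not reflect members that vary together more than preset. As for the photosynthesis list, the degrees of freedom then came from the arrays and not from the genes.

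Genes of the chromosome 4 stretch were higher together, and 0 of 1000 shuffles of gene order gave a window of 20 genes with a median as high as 0.89 (highest shuffled 0.31), which argues against chance placement. Probes that mismatch another accession's sequence should shift only some genes, or both ways; when the stretch was delimited on every other gene and measured on the 31 genes between, 87.1% of these had a log2 ratio over 0.5, against 4.87% on average in shuffled orders. A candidate explanation is an extra copy of the segment in hub2-3, but its bounds were set after the median of 0.87 was seen and it cannot be told apart from an effect of the genotype on the transcription of this region, as the arrays measure RNA and no DNA was examined. The 20 measured genes around HUB2, on chromosome 1, had a median of -0.01, and the highest window outside the stretch had 0.18.

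Of 12 transcripts of the mitochondrial genome, 6 were lower in hub2-3 and 0 higher, with a median of -0.57 (camera, adjusted p = 9.58e-06). With an estimated correlation of 0.051, above the preset 0.01, the call was lost (camera, adjusted p = 0.212). The 25S rRNA control was lower on the same arrays. Some of the mitochondrial transcripts had been seen to be lower before the family was set. The bound set against RNA degradation was at least 1 hub2-3 array at or below the Col mean of the 3 prime over 5 prime ratio. Replicate 3, with a mitochondrial median of -0.48, met it by only -0.010, within the Col SD of 0.04. Replicates 1 and 2 both stood at 1.17, above the Col mean of 0.97. With 1 array deciding the bound, RNA degradation cannot be told apart from an effect of genotype. Less organelle RNA without poly(A) tails in the labelled cRNA should lower chloroplast transcripts as much; these differed from mitochondrial ones by 0.39 (95% bootstrap interval 0.15 to 0.65), which met the bound set against it. It stays open all the same, since the interval covers genes and not arrays: chloroplast medians were -0.65, -0.059 and 0.17 in hub2-3 replicates 1, 2 and 3 beside mitochondrial medians of -0.76, -0.52 and -0.48, so that replicates 2 and 3 go against it, 0 of 69 chloroplast genes passed, and the difference between both medians per array was not set apart from Col (2-sided exact permutation p = 0.2, where 0.1 is the smallest possible).

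Genes known to respond to low oxygen were lower: of 22 measured members of a list of 49, 9 had been seen to change before the list was written (8 of them lower), so the other 13 were tested alone. Of these 13, 7 passed as lower, among them AT4G27450 at 1.82-fold and AT5G66985 at 1.61-fold, AT3G23170 passed as higher, and 5 did not pass: PDC2, AT1G19530, AT4G17670, AT5G42200 and AT5G44730. Their median of -0.42 lay below the central 95% of 10000 random lists matched on signal (-0.15 to 0.12), which argues against the choice of members as the whole cause. Without CML38, whose family median had been seen, the median was -0.34. The range covers lists of genes drawn singly and not arrays, so it can be too narrow for members that vary together. The same comparison, which is not a second test, also bears on scaling between arrays: scaling should shift genes of the same signal alike, and the 13 lay at -0.41 relative to the median of the matched lists. No test here separated an effect of the genotype from a difference in how the seedlings were grown or harvested.

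A hypothesis that longer genes are lower in hub2-3 was tested across genes, which are not independent replicates. Spearman's rho of log2 ratio with annotated gene span was 0.17 over 8469 genes, opposite in sign to the hypothesis, though another split of the arrays reached 0.16, and 10 splits are too few to set chance aside, so the hypothesis stays open. Of genes in the shortest quartile of span 8.59% were called lower, against 1.18% in the longest quartile, while 4.72% and 5.24% were called higher; these shares come from the same log2 ratios as rho and add no test of their own.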
